A study of Mus musculus with 9 samples.

How the data were processed

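Total RNA was taken from 9 mouse samples with a column kit, and 100 ng of each was amplified, labelled with biotin and hybridised to single-colour Illumina bead arrays, per the labels' protocols. The sample titles gave the groups and replicate numbers: 3 samples of the untreated line C17.2 (NSC), 3 of the line after mitomycin (MMC) and 3 of primary neuronal cultures (PNC). No label names an array batch, and nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

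The deposited raw table holds 1 mean bead intensity per probe and array on a linear scale. BeadStudio is named for it per the submitters' processing notes, while its version and any background step are not given in the sources used here. All its values were positive, with a lowest intensity of 32.8 and array medians from 61.6 to 69.2, and the quantiles differed between arrays, so it was treated as neither background-corrected nor normalised. The deposited series matrix holds the authors' processed intensities of the same arrays. Set against the raw table, each of its columns correlated best with its own array (Pearson's r across probes on the log2 scale at least 0.999), and its values were on a linear scale, not centred by gene, with array medians from 65.2 to 65.8. The method of that normalisation is not given in the sources used here, and the matrix served as an alternative.

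Of 45281 probes, 36913 were named through a gene table of the mouse assembly GRCm38.p6, used for names only, and 8368 kept the symbol given in the raw table. The symbols of 9233 probes changed in this step. The analysis as planned took its background and its detection from the detection p-values of the array software, which were not used here. In their place, 1619 probes for olfactory, vomeronasal and trace amine-associated receptors and for beta-defensins, genes with little transcription outside their own organs, stood in for negative controls. Their intensities gave the background for limma's normexp correction with an offset of 16, followed by quantile normalisation and log2. A probe was counted as detected on an array above the 99th percentile of these probes (p of 0.01). This share, 38.7% to 45.4% of probes per array, thus rests on the assumption that these receptor and defensin genes were silent.

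Probes detected on at least 3 of the 9 arrays were tested, 21187 in all, and a gene with several such probes (4814 genes) was represented by the probe with the highest mean. This left 14057 genes, of which 9825 were detected on all 9 arrays. Probes of the same gene were called in opposite directions for 45 genes in MMC against NSC, 379 in PNC against NSC and 343 in PNC against MMC. One linear model per gene with the group as its only term was fitted to the 9 arrays in limma 3.58.1 under R 4.3.3, with 6 residual degrees of freedom, and moderated by empirical Bayes. The 3 comparisons were taken as contrasts of this model. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. Where a gene was not detected on any array of a group, the text gives an "at least" fold: the mean of the brighter group over the mean of, per array, the higher of the probe's own value and the lowest value among detected probes. No such fold is given where this bound is not exceeded. With 3 arrays per group, the number of arrays limits the precision, and the median standard error of a log2 fold change was 0.13.

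Gene lists were tested with limma's camera with a preset correlation between genes of 0.01, two-sided and adjusted over 26 lists per comparison. The test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way without comparing them with other genes. The lists were neuronal structure, synapse, glutamatergic, GABAergic, neurogenic transcription factors, neural stem and progenitor, G1/S and DNA replication, G2/M and mitosis, p53 targets, cell cycle inhibitors, crosslink and homologous recombination repair, secreted factors of senescent cells, interferon response, lysosome, cholesterol synthesis, Myc targets and ribosome biogenesis, ion pumps and pH regulators, astrocyte, oligodendrocyte lineage, microglia, endothelial and mural, mesenchymal and extracellular matrix, and reference genes. Solute carriers, voltage-gated ion channels and ribosomal proteins were listed by the form of their symbols. The channel list took all symbols starting with Kcn or Cacn, or with Scn or Hcn and a digit. It was not restricted to channels gated by voltage, despite its name. Of 536 symbols listed one by one, 526 were on the array.

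The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison, the 4 highest and 4 lowest fold changes among called genes detected on all arrays of both groups without overlap, the 3 highest and 3 lowest "at least" folds, a set of check genes, and for each list past its threshold or with at least 3 called members the 2 called members with the strongest change in each direction, or all called members where there are 5 or fewer. For genes changed against NSC in both MMC and PNC it takes the 5 per direction with the largest smaller change. Clone and predicted symbols were passed over, and some genes that the rule takes are not reported here. Snap25, a check gene, was not tested because its probes did not pass the detection filter.

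The procedure was tested on simulated arrays with the means and spread of the real ones and 200 changed genes. It recovered 16.4%, 17.9% and 22.4% of 1.5-fold changes in MMC against NSC, PNC against NSC and PNC against MMC, 56.7%, 65.7% and 65.7% of 2-fold changes, and 95.5%, 95.5% and 97.0% of 4-fold changes, and it called 6, 6 and 7 unchanged genes, on 11803, 11808 and 12147 genes. A shifted list was called in each comparison and 0 of 25 unchanged lists were. The simulated noise was independent between probes, so lists of correlated genes were not tested (estimated correlation of 0.82 for G2/M and mitosis). Nor were changes in as many genes as the real comparisons called.

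The alternatives were no background correction, an offset of 50, median scaling of detected probes, cyclic loess, the series matrix, no filter on dim probes, detection on all 9 arrays, the mean of a gene's probes, only the 2 groups compared, the replicate number as a block, trended and robust moderation, array weights, an added threshold of 2-fold, and leaving out each array in turn. An estimate of the background from the lower side of each array's signal mode was added after seeing the data. Overlaps between comparisons that share the NSC arrays were set beside 100 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9 and tables prepared with pandas 2.3.3 under Python 3.11.15.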

Results

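Gene expression was measured on single-colour bead arrays in 9 mouse samples, 3 from each of 3 kinds of culture. NSC denotes C17.2, a proliferating neural stem cell line of mixed C57BL/6J and CD1 origin, immortalised with c-myc and carrying a LacZ marker, sampled after 3 to 4 days in culture at 50% confluency. MMC denotes the same line treated with mitomycin, a compound that crosslinks DNA and blocks its replication, sampled after 8 days in culture. PNC denotes primary neuronal cultures from brains of C57BL/6J embryos of day 17, made from 1 to 2 litters per experiment and sampled after 8 days. Treatment and time in culture therefore differ together between NSC and MMC. Between PNC and the line, cell type, strain and immortalisation differ together, and against NSC also time in culture. No sample parts these.

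The arrays separated by group. The first principal component held 90.9% of the variance and set the PNC arrays (scores of 150 to 165) apart from all arrays of the line (-82.9 to -78.1). The second, with 6.24%, set the MMC arrays (35.0 to 37.5) apart from the NSC arrays (-36.7 to -35.4). The correlation between arrays of a group, across genes, lay between 0.984 and 0.997. The median standard deviation of a gene within a group was 0.10 on the log2 scale in NSC, 0.17 in MMC and 0.14 in PNC. Expression values below are means of normalised log2 intensities ± SD with n = 3 arrays per group, and fold changes of dim genes on this scale depend on the background correction.

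The comparison of MMC with NSC asks how expression in the line differed after mitomycin treatment and a longer time in culture. Genes of DNA replication and mitosis fell, while p53 targets, factors secreted by senescent cells and lysosomal genes rose. These lists passed camera, a test for a shift of a list, with its preset correlation between genes. With an estimated correlation the calls of these lists were lost (adjusted p = 0.0786, 0.309, 0.228, 0.309 and 0.0958 for replication, mitosis, p53, secreted factor and lysosome lists). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose 3.99-fold, from 10.80 ± 0.04 in NSC to 12.79 ± 0.18 in MMC (limma adjusted p = 1.4e-05). Mki67, a marker of proliferating cells, fell by 2.51 on the log2 scale, from 10.61 ± 0.07 to 8.10 ± 0.51 (adjusted p = 2.3e-05). No list of neuronal genes passed camera, although the synapse list did in fry, a second list test (adjusted p = 0.0451). In each of these lists, 9 to 13 genes were detected in neither group, which limits the test. Gap43, a protein of growing axons, and Syn1, a synaptic vesicle protein, were detected on no array of either group. Of 14057 genes, 2742 were higher and 2746 lower in MMC in limma, 665 and 562 of them by at least 2-fold, and the values of the 2 groups did not overlap for 51.9% of genes, where chance gives 10%. The balance depends on the scaling: the counts were 3393 and 2292 with cyclic loess and 3191 and 2573 in the authors' matrix.

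All 27 measured genes of the G2/M and mitosis list fell, with a median log2 fold change of -1.82. Ccnb1, the mitotic cyclin B1, changed by -1.82 (SE 0.26, limma adjusted p = 0.00043) and Top2a, the topoisomerase that untangles replicated chromosomes, by -1.52 (SE 0.28, adjusted p = 0.002). Cyclin A2, Ccna2, was detected on 2 of 3 MMC arrays and changed by -2.72. Of the G1/S and DNA replication list, 27 of 28 genes fell (median -1.67), among them Tk1, thymidine kinase (-2.65, SE 0.17), and Mcm5, a subunit of the replicative helicase (-2.24, SE 0.12). Genes that repair DNA crosslinks and breaks by homologous recombination also fell, 15 of 19 with a median of -1.36. Among these, Rad54l fell by 2.43, and Fanca, of the Fanconi anaemia pathway, was at least 2.35-fold lower and not detected in MMC. Adjusted over the list alone, the counts were the same 27, 27 and 15. With camera the adjusted p was 1.7e-16, 7.49e-19 and 3.78e-09 for the 3 lists, and adjusted p = 0.309, 0.0786 and 0.0958 with an estimated correlation. Mybl2, a transcription factor of cycling cells (-3.40, SE 0.13), and Sapcd2 (-3.22, SE 0.19) were among the lowest called genes, and Knl1, a kinetochore protein, was at least 3.27-fold lower. The muscle form of fructose bisphosphatase, Fbp2, was at least 4.04-fold lower. Histone genes lay at both ends: H2ac11 and H2ac15 fell by 3.45 and 3.15, H3c3 was at least 6.94-fold lower, and H2ac19 rose 8.10-fold, although probes of histone genes share sequence between near-identical copies and the gene behind each signal is uncertain.

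Of 28 p53 targets, 19 rose and 0 fell (median 0.71; 6646 genes had an unadjusted p under 0.05 in this comparison). Fas, a death receptor, rose 4.56-fold (9.88 ± 0.59 against 7.69 ± 0.12, adjusted p = 0.00013), and Gadd45a, a stress-induced growth arrest gene, rose 3.91-fold (13.11 ± 0.41 against 11.14 ± 0.09). Of 27 secreted factors of senescent cells, 17 rose (median 1.17). The matrix metalloproteinase Mmp10 rose 7.62-fold, and Mmp12, not detected in NSC, was at least 6.13-fold higher. The lysosome list rose in 22 of 25 genes (median 0.77), with Psap, the precursor of the saposins, at 1.05 (SE 0.10) and the protease Ctsl at 1.25 (SE 0.17). Of 16 interferon response genes, 8 rose (median 0.64), led by the GTPase Gbp2 (8.26-fold) and Oasl2 (at least 1.98-fold). Adjusted over the list alone, 19, 17, 23 and 9 genes of these 4 lists rose. Their adjusted p in camera was 1.03e-07, 5.08e-07, 1.85e-10 and 0.00122, and adjusted p = 0.228, 0.309, 0.0958 and 0.523 with an estimated correlation. The interferon median fell to 0.42 without MMC replicate 2, and the call ended when only genes detected on all 9 arrays were tested (median 0.38, adjusted p = 0.0632).

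Among the highest increases outside these lists, Dcn, which encodes the matrix proteoglycan decorin, rose 18.3-fold (13.80 ± 0.36 against 9.60 ± 0.16, limma adjusted p = 1.9e-06), and Il33, an alarmin cytokine, rose 9.12-fold (adjusted p = 4.6e-06). Not detected in NSC, Prl2c3, a member of the prolactin family, was at least 21.1-fold higher, Bglap2, of the osteocalcin genes, at least 18.9-fold and S100a8, a calcium-binding protein of myeloid cells, at least 11.5-fold. Prl2c3 and Bglap2 have near-identical copies, which leaves the gene behind each signal uncertain. The mesenchymal list held 9 higher and 2 lower genes of 22 and missed the threshold (median 0.31, adjusted p = 0.069), but its median was 0.74 without MMC replicate 3, a call in that setting, and 0.14 without MMC replicate 2 (adjusted p = 0.188). It also passed without the filter on dim probes (0.24, adjusted p = 0.0244). The connective tissue growth factor Ccn2 rose by 2.31 with a wide spread in MMC (11.30 ± 1.39, and 1.59 without replicate 2 or 2.97 without replicate 3), while the collagen gene Col1a2 and Tgfbi fell by 1.59 and 1.19.

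Genes of cholesterol synthesis fell, 13 of 21 with a median of -0.62 and 15 when adjusted over the list alone. Idi1, isopentenyl diphosphate isomerase, changed by -1.62 (SE 0.11, limma adjusted p = 4.3e-06), and Mvk, mevalonate kinase, was at least 2.29-fold lower. Myc targets and ribosome biogenesis genes fell in 13 of 28 cases (14 when adjusted over the list alone, median -0.48), with Tfrc, the transferrin receptor, at -1.74 (SE 0.26) and Ppat, of purine synthesis, at -1.13 (SE 0.10). For these lists camera gave an adjusted p of 1.82e-06 and 3.31e-05, and adjusted p = 0.218 and 0.625 with an estimated correlation. Myc itself was detected on 2 of 3 MMC arrays and no NSC array (at least 1.06-fold higher), and its call at 0.85 was lost without NSC replicate 1 (0.82) or 2 (0.67) or MMC replicate 1 (0.86) or 2 (0.58). The line was immortalised with c-myc, and whether the Myc probe reads the introduced gene was not tested. Of 225 solute carrier genes, 62 rose and 26 fell, the same when adjusted over the list alone (median 0.08, adjusted p = 0.0482, and adjusted p = 0.309 with an estimated correlation), among them Slc22a18 (at least 2.14-fold higher) and the monocarboxylate transporter Slc16a7 (-1.57, SE 0.12). That call was also lost without NSC replicate 2 (median 0.10), MMC replicate 3 (0.07) or any single PNC array (0.08), with an adjusted p of up to 0.116 over the alternatives.

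Lists of neural cell types did not pass the test in MMC, although single members did. No array of NSC or MMC detected 9 of 23 neuronal structure, 11 of 27 synapse and 11 of 16 glutamatergic genes. The same held for 12 of 15 GABAergic genes and 13 of 19 neurogenic factors. Changes of such genes lie near background, so the tests say little about them. Of 23 genes of neuronal structure, 3 rose and 1 fell. Eno2, neuronal enolase, rose 4.32-fold and Map2, a dendritic microtubule protein, fell by 1.61 (9.04 ± 0.38 against 10.65 ± 0.11, limma adjusted p = 0.00012). Rbfox3 was called at 0.39 while not detected in either group. Its call was lost without NSC replicate 2 (0.37), with an offset of 50 (0.15) and with the mean of its probes (0.25). The call of Nsg1 at 0.58 was lost without any one of the NSC arrays, MMC replicates 1 or 2 or PNC replicates 2 or 3 (0.42 to 0.67). Of 27 synapse genes, 6 rose and 1, Camk2b, fell, with a change of -0.60 (-0.40 without MMC replicate 3), a call lost without NSC replicate 3 (-0.55). Syt4, a synaptotagmin, rose 3.08-fold. Of 16 glutamatergic genes, Gria1 and Gria4, AMPA receptor subunits, rose and Grik2, a kainate receptor subunit, fell. Gad1 rose and Dlx1 fell of 15 GABAergic genes, with Gad1 detected in neither group and its call (0.44) lost with an offset of 50 (0.18) and with the mean of its probes (0.21), and Sox4 rose and Sox11 fell of 19 neurogenic transcription factors, where Dlx1 and Sox4 are named after their values were seen. Among 18 stem and progenitor genes, 3 rose and 4 fell. Nes, the intermediate filament nestin, rose 1.88-fold and Sox9 1.91-fold, and Hey1, a Notch target, fell by 1.61. Sox2 (0.17, adjusted p = 0.61), Vim (0.24, adjusted p = 0.11) and Mapt (0.28, adjusted p = 0.13) were not called in the main fit. Vim was called with cyclic loess (0.31, limma adjusted p = 0.039) and in the authors' matrix (0.30, limma adjusted p = 0.0287). Sox2 and Vim were called without MMC replicate 2 (0.48 and 0.32), and Mapt was called without MMC replicate 3 (0.45). Sox2 turned to -0.05 without MMC replicate 3, and Mapt was 0.16 without MMC replicate 2. The adjusted p of the lists of neuronal structure, synapse, glutamatergic, GABAergic, neurogenic and stem cell genes was 0.753, 0.142, 0.949, 0.786, 0.965 and 0.786. The synapse list passed without the filter on dim probes (median 0.09, adjusted p = 0.0447), and in fry the synapse and stem cell lists did (adjusted p = 0.0451 and 0.0397). Adjusted over the list alone, 2 genes of neuronal structure and 0 neurogenic factors rose, with the other counts of these 6 lists the same.

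Of the remaining lists, cell cycle inhibitors rose in 6 and fell in 2 of 13 genes (adjusted p = 0.0714), the 2 being Rbl1 and Cdkn2c at -1.17 and -0.88. That list, with a median of 0.54, was called without MMC replicate 3 (0.53) or without PNC replicate 1 (0.54), and without the filter on dim probes (0.42, adjusted p = 0.0103). Astrocyte genes rose in 3 (S100b, Slc1a2 and Gja1) and fell in 2 of 15 cases (adjusted p = 0.824). The falling genes were Apoe (at least 1.15-fold lower), whose call at -0.55 was lost without NSC replicate 1 (-0.39) or MMC replicate 1 (-0.44), and Sparcl1 (-0.67), not called without any one array other than MMC replicate 1 (-0.78 to -0.49). S100b, a calcium-binding protein of glia, rose 5.71-fold. In the oligodendrocyte list 1 gene, Pdgfra, rose and 2, Gpr17 and Mbp, fell of 11 (adjusted p = 0.965), with a median of 0.07 and a mean of -0.10. Of 6 microglia genes 3 rose (adjusted p = 0.161), among them the lysosomal and phagocyte genes Cd68 (7.06-fold, a log2 change of 2.82 that was 2.21 without MMC replicate 2) and Laptm5 (4.15-fold). The microglia list, with a median of 0.37, passed when only genes detected on all 9 arrays were tested (2.05, adjusted p = 0.0143). In fry the cell cycle inhibitor, microglia, endothelial and reference lists passed (adjusted p = 0.0266, 0.0152, 0.0431 and 0.0463). Of 8 endothelial and mural genes Pdgfrb and Flt1, named after their values were seen, rose (adjusted p = 0.435). Ion pumps rose in 5 and fell in 3 of 23 genes (adjusted p = 0.515), ion channels listed by symbol in 7 and 6 of 77 (0.949), and ribosomal proteins in 2 and 7 of 63 (0.227, median -0.06, and 0.02 and 0.05 after median scaling and cyclic loess). Among 14 reference genes Eef2 rose (0.72) and 4 fell (adjusted p = 0.515), among them Tfrc, Rpl13a (-0.46) and Tbp, with Eef2 and Rpl13a not called without NSC replicate 1 (0.64 and -0.45) and Tbp not called by the mean of its probes (-0.25). Adjusted over the list alone, 7 cell cycle inhibitors and 5 channels rose and 1 astrocyte gene, 3 channels and 6 ribosomal protein genes fell, with the other counts of these lists the same. In limma with array weights the counts of the whole comparison were 4702 higher and 4692 lower genes, and no list stayed past the threshold with an estimated correlation.

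**Figure D1:**
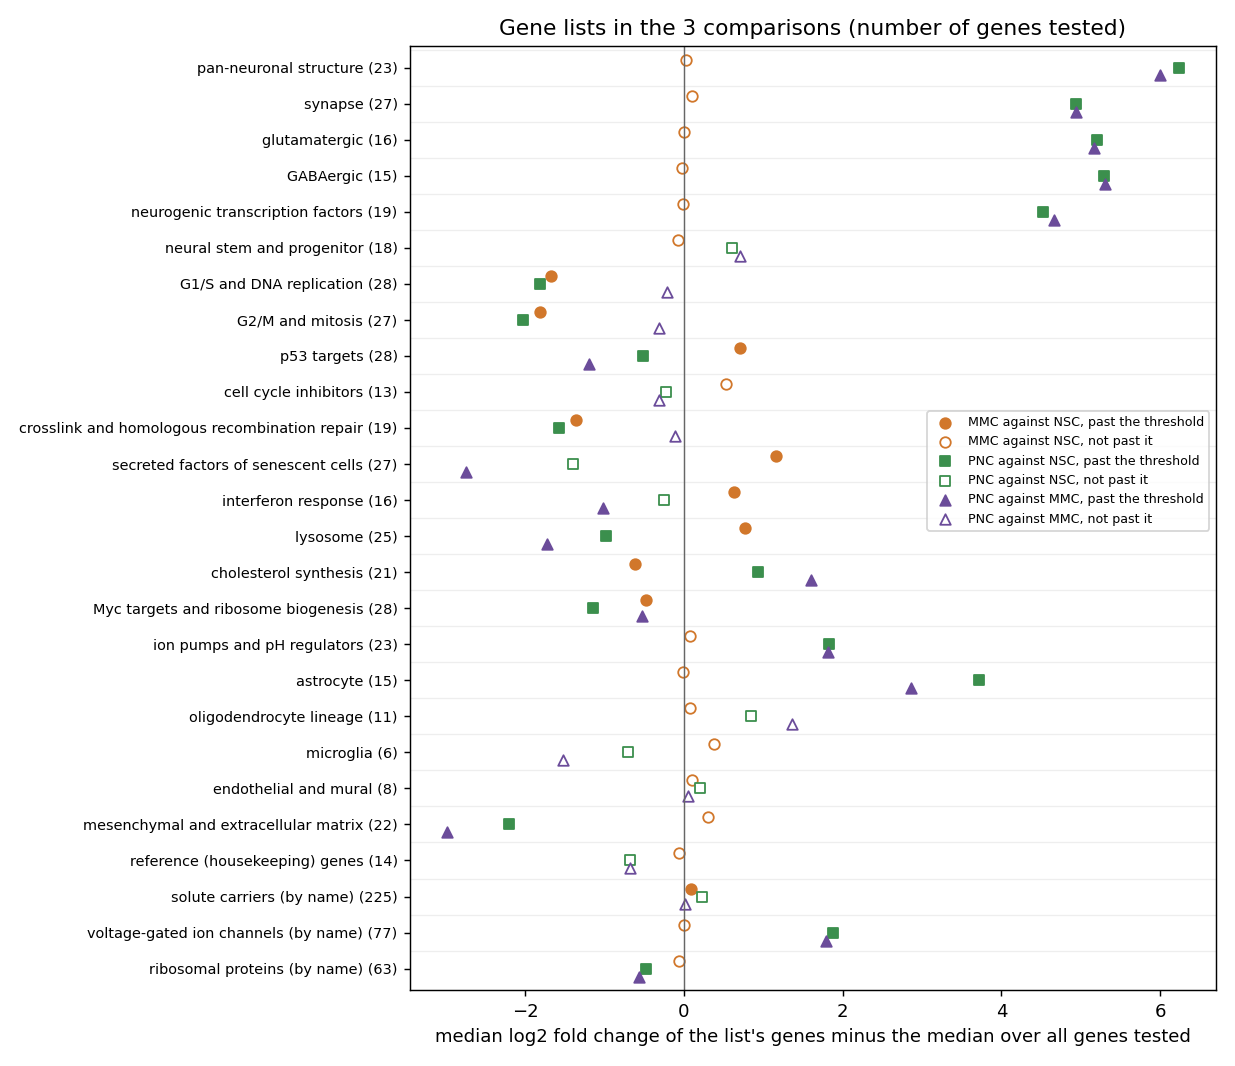
Median log2 fold change of each gene list relative to the median of all genes (x axis) in the 3 comparisons, with filled points for lists past the camera threshold and open points for the others. In MMC against NSC the lists of G2/M and G1/S genes lie lowest (-1.82 and -1.67), whereas in PNC against NSC neuronal structure lies highest (6.24).

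The comparison of PNC with NSC sets primary neuronal cultures against the proliferating line. Neuronal genes were higher in PNC by factors of up to at least 650, astrocyte genes were higher too, and genes of the cell cycle, the lysosome and the extracellular matrix were lower. With an estimated correlation the calls of the G1/S, G2/M, lysosome and mesenchymal lists were lost (adjusted p = 0.101, 0.419, 0.248 and 0.62). Stmn2, a microtubule regulator of growing axons, stood at 15.01 ± 0.01 in PNC and was not detected in NSC, at least 650-fold higher (limma adjusted p = 7.8e-13). Gap43 was at least 524-fold higher and Fxyd6, a regulator of the sodium pump, at least 538-fold. Gad1, the enzyme that makes GABA, was at least 163-fold higher, and Gfap, the intermediate filament of astrocytes, at least 24.2-fold. Of 14057 genes, 5115 were higher and 6362 lower in limma, 3309 and 3585 of them by at least 2-fold, and the groups did not overlap for 85.7% of genes, where chance gives 10%. The higher genes outnumbered the lower with other scalings, 5981 to 5108 after median scaling, 6087 to 5070 with cyclic loess and 5856 to 5448 in the authors' matrix.

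The median log2 fold change of all genes was -0.18 in this comparison, against 0.08 after median scaling, 0.10 after cyclic loess and 0.01 with the authors' matrix, so medians of lists are given relative to that of all genes. Of 23 genes of neuronal structure 22 rose (relative median 6.24), of 27 synapse genes 25 (4.94), of 16 glutamatergic genes 15 (5.21), and all 15 GABAergic genes (5.30) and all 19 neurogenic transcription factors (4.52). Mapt, the axonal protein tau, rose 66.6-fold (14.93 ± 0.06 against 8.87 ± 0.03), Map2 7.66-fold and Tubb3, neuronal beta-tubulin, at least 2.69-fold. Syt1, the calcium sensor of vesicle release, was at least 291-fold higher, Cplx1, a complexin, at least 215-fold, and Syn1 at least 161-fold. The glutamate receptor subunit Gria2 was at least 120-fold higher, the vesicular glutamate transporter Slc17a7 at least 6.31-fold, and the interneuron peptide Sst at least 246-fold. Among transcription factors, Myt1l was at least 141-fold and Bcl11b at least 103-fold higher. Against the direction of the synapse list, Bsn, a protein of the presynaptic zone, was at least 1.66-fold lower. Shank2 fell by 0.53 with a call lost without NSC replicate 1 (-0.43) or PNC replicate 1 (-0.52) or 3 (-0.37) and after median scaling (-0.11) or cyclic loess (-0.22). Ion channels listed by symbol, not all of them gated by voltage, rose in 58 and fell in 7 of 77 genes (1.88). The potassium channels Kcnd2 and Kcnk5 stood at least 75.0-fold higher and at -4.23. With genes not detected in NSC set at their bound, the median log2 fold changes of these 6 lists were 5.64, 3.98, 3.68, 3.84, 3.20 and 1.18. Camera gave an adjusted p of 3.36e-10, 3.36e-10, 7.16e-07, 4.48e-08, 1.71e-09 and 1.71e-09, and adjusted p = 0.0275, 0.0451, 0.0555, 0.0275, 0.0275 and 0.0275 with an estimated correlation.

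Among the highest called genes detected in both groups were Sybu, which links vesicles to kinesin (123-fold), Rufy3 (111-fold) and Camk2b, a calcium-dependent kinase of synapses (108-fold). At the other end stood Gpnmb, a membrane glycoprotein (7.40 ± 2.19 against 14.15 ± 0.03, with a log2 change of -6.74 that was -8.01 without PNC replicate 1, -6.09 without 2 and -6.13 without 3). With it stood Capn6, a calpain relative (-6.38, SE 0.29), Capg, an actin-capping protein (5.92 ± 1.08 against 12.21 ± 0.08, with -6.29 and -6.91 without PNC replicate 1), and Cdkn2a, whose products p16 and p19 restrain cell division (-6.28, SE 0.27). Not detected in PNC, the surface protein gene Ly6c1 was at least 62.6-fold, the troponin gene Tnnc2 at least 50.1-fold and the zinc finger gene Zfp985 at least 47.5-fold lower.

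Astrocyte genes rose in 13 and fell in 2 of 15 cases (relative median 3.71, adjusted p = 0.000146, and adjusted p = 0.0451 with an estimated correlation). The glutamate transporter Slc1a3 was at least 214-fold and the water channel Aqp4 at least 57.2-fold higher, whereas S100b was at least 3.17-fold lower and the gap junction gene Gja1 fell by 0.97. In the oligodendrocyte list 6 genes rose and 4 fell of 11 (relative median 0.84, adjusted p = 0.311). Its median of 0.66 turned to -3.65 over the genes detected on all 9 arrays. Olig1 was at least 486-fold higher in PNC, while Sox10, a transcription factor of oligodendrocytes and neural crest, was bright in NSC (12.91 ± 0.07) and changed by -4.68. Of 6 microglia genes Fcer1g (at least 1.09-fold) and Aif1, not detected in NSC and too dim in PNC for a fold, rose and 4 fell, among them Cd68 with a change of -1.59 (-0.84 and not called in the authors' matrix, adjusted p = 0.783 for the list). The microglia median of -0.88 turned to 0.10 without the filter on dim probes. Of 8 endothelial and mural genes 3 rose and 3 fell, with Slco1c1 at least 8.17-fold higher and Flt1 at least 17.3-fold lower (adjusted p = 0.833, with a median of 0.02 and a mean of -0.52). Stem and progenitor genes moved both ways, 9 higher and 6 lower of 18 (relative median 0.61, adjusted p = 0.383). Fabp7, a lipid-binding protein of radial glia, rose 50.2-fold, the Notch target Hes5 was at least 16.3-fold higher and Sox2 rose 1.88-fold, while Nes (-2.04), Vim (-2.29) and the hyaluronan receptor Cd44 (-3.54) fell.

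Genes of the cell cycle fell: 27 of 27 G2/M and mitosis genes (relative median -2.03), 27 of 28 G1/S and replication genes (-1.82) and 17 of 19 recombination repair genes (-1.58). Mki67 stood at 8.62 ± 0.26 in PNC against 10.61 ± 0.07 in NSC (adjusted p = 1.1e-05), and the changes were -2.13 for Top2a, -1.93 for Ccnb1, -3.25 for the mitotic kinase Cdk1, -3.49 for Tk1, -3.30 for Cdt1, which licenses replication origins, and -2.82 for Brca1. With an estimated correlation adjusted p = 0.419, 0.101 and 0.143 for these lists, after 1.17e-06, 2.82e-07 and 0.00017 with the preset one. The inhibitors of the cell cycle moved both ways, 5 higher and 7 lower of 13 (adjusted p = 0.893). Cdkn1c, p57, was at least 16-fold and Cdkn2b, p15, at least 5.50-fold higher. Cdkn1a changed by -0.41, a call lost without PNC replicate 2 (-0.29) or 3 (-0.33) or any one NSC array (-0.43 to -0.40), and by -0.02 in the authors' matrix.

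Further lists shifted as well. Of 28 p53 targets 4 rose and 18 fell (relative median -0.52), among them Dram1 (-3.59) and Gadd45a (-2.74), with Plk2 up at 1.21. Lysosome genes fell in 21 and rose in 2 of 25 cases (-0.98), the cathepsin Ctsz with a change of -4.70, and with the proton pump subunits Atp6v0d1 and Atp6v1h up at 1.41 and 0.80. Of 22 mesenchymal genes 16 fell and 3 rose (-2.20), among them Tgfbi (-5.01) and Snai2 (-4.28), while Lum, lumican, was at least 9.14-fold higher. Myc targets fell in 20 of 28 cases and rose in 0 (-1.15), with Wdr43 at -2.59 and Ppat at -2.51, and 11608 genes had an unadjusted p under 0.05. Ribosomal protein genes fell in 46 and rose in 4 of 63 cases (-0.47), among them Rpl13a (-2.89), while Rps4l was at least 8.03-fold higher. These 5 lists had an adjusted p of 0.0227, 0.0009, 0.0297, 0.00104 and 0.000195 in camera, and adjusted p = 0.439, 0.248, 0.62, 0.472 and 0.325 with an estimated correlation. Ion pumps and pH regulators rose in 14 and fell in 4 of 23 cases (1.82), with the sodium pump subunits Atp1b1 up 84.4-fold and Atp1b2 at least 43.0-fold. Cholesterol synthesis rose in 14 and fell in 4 of 21 (0.94), with Idi1 up 4.72-fold and Ebp down at -2.07. Their adjusted p was 0.0047 and 0.0392, and adjusted p = 0.114 and 0.419 with an estimated correlation. Adjusted over the list alone, the counts were the same for all 26 lists. Secreted factors of senescent cells (6 higher, 18 lower of 27, adjusted p = 0.0968), interferon genes (4 and 8 of 16, 0.383), solute carriers (98 and 83 of 225, 0.175) and reference genes (2 and 10 of 14, 0.0609) missed the threshold. Among their members Igfbp2 was at least 42.3-fold and Slc32a1, a GABA transporter, at least 127-fold higher. Ccl7, Ifitm3 and Gusb changed by -5.80, -4.33 and -4.20. The reference list passed it without PNC replicate 3 (median -0.97, and -0.86 with all arrays), and after median scaling and cyclic loess, and Actb was higher by its brightest probe (0.59) and lower by the mean of its probes (-1.28).

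Transcripts that were bright in the line appeared at a low level on the array of PNC replicate 1. Over 43 probes above 1000 intensity units over background in NSC and MMC and not detected on PNC replicates 2 and 3, the excess of PNC replicate 1 over the mean of the other 2 had a median of 2.10% of the level of the line. That excess ranged from -0.38% to 8.80% between probes. Mesenchymal, secreted factor, microglia and cell cycle inhibitor genes moved with it: their medians against NSC were -1.69, -1.22, -0.53 and -0.02 on PNC replicate 1, and -2.64, -1.72, -1.0 and -0.65 on replicate 2 and -2.49, -1.61, -1.12 and -0.88 on replicate 3. Without PNC replicate 1 the secreted factor list was called (median -1.75, and -1.58 with all arrays), as it was after median scaling and cyclic loess. As limits, the calls of the p53, ion pump and astrocyte lists ended when only genes detected on all 9 arrays were tested (adjusted p = 0.0866, 0.0878 and 0.125), with the p53 median at -0.70 in both settings while those of the other 2 went from 1.64 to 0.02 and from 3.53 to 1.49. This filter also left 2955 genes higher in PNC. The call of cholesterol synthesis, with a median of 0.76, ended without NSC replicate 2 (0.75) or PNC replicate 3 (0.55) and that of the mesenchymal list with the mean of a gene's probes (adjusted p = 0.0626).

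**Figure D2:**
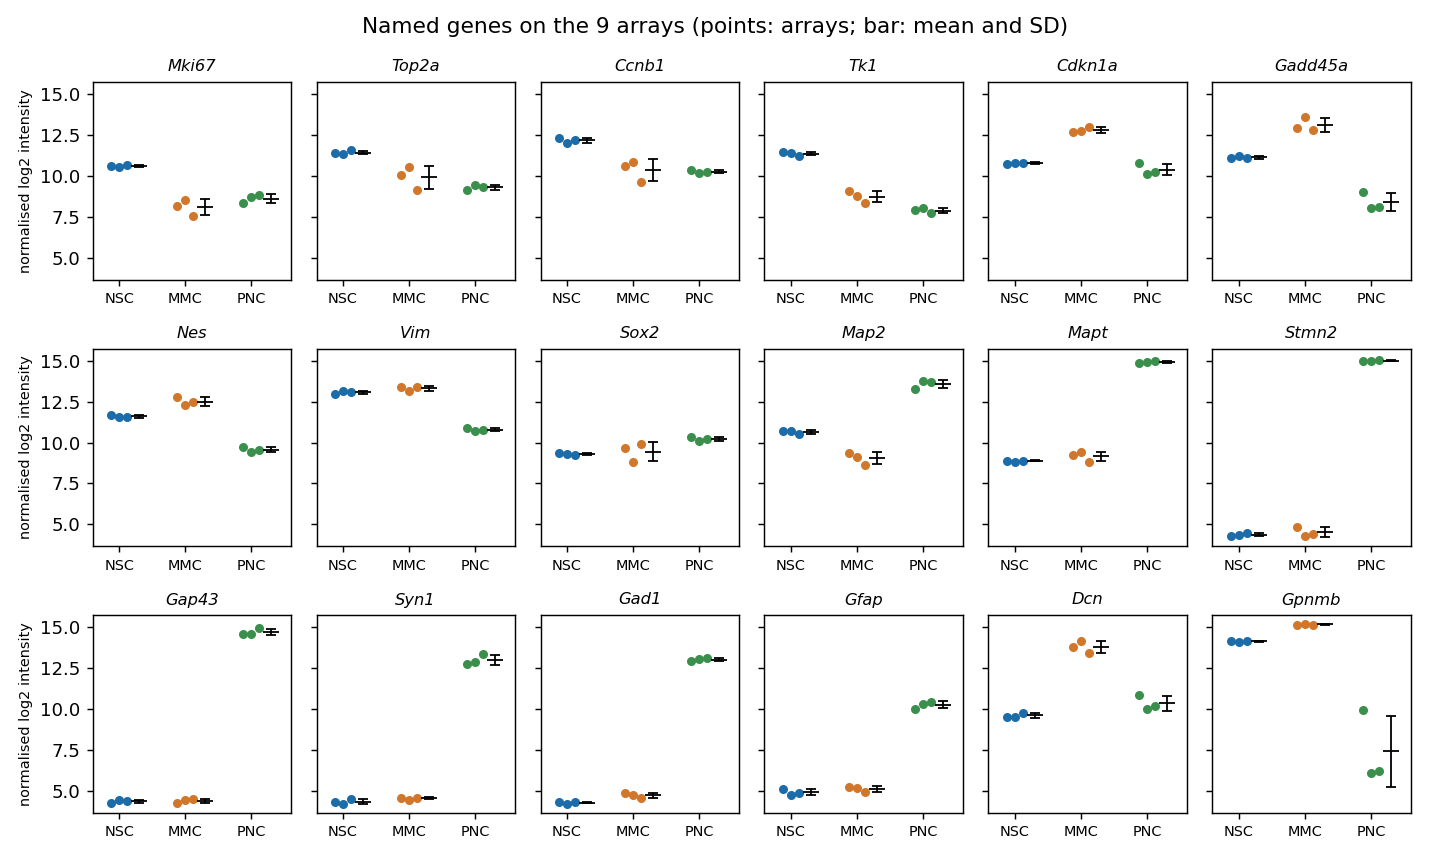
Normalised log2 intensity (y axis) of 18 named genes on the 9 arrays by group, with a point per array and a bar for the mean with its SD. Stmn2 lies at background in NSC and MMC (4.35 and 4.52) and at 15.01 in PNC, and Gpnmb has the wide spread in PNC (SD 2.19).

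The comparison of PNC with MMC asks what still separates the mitomycin-treated line from primary neuronal cultures. Neuronal genes were higher in PNC here too, and no list of cell cycle genes passed camera. The p53, secreted factor and lysosome lists, which had risen in MMC, shifted lower in PNC, though not in every gene. With an estimated correlation these 3 calls were lost (adjusted p = 0.223, 0.35 and 0.113). Stmn2 was at least 695-fold higher in PNC (limma adjusted p = 8.3e-13), Cdkn1a fell by 2.41 (10.39 ± 0.34 against 12.79 ± 0.18, adjusted p = 1.6e-07), and Mki67 differed by 0.53 (8.62 ± 0.26 against 8.10 ± 0.51, adjusted p = 0.051). In limma 5145 genes were higher and 5979 lower in PNC, 3197 and 3347 of them by at least 2-fold, and the groups did not overlap for 79.6% of genes, where chance gives 10%. Here too the balance turned, to 5985 higher and 4949 lower after median scaling, 5951 and 5041 with cyclic loess and 5795 and 5311 in the authors' matrix.

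Of 23 genes of neuronal structure 21 rose (relative to a median of all genes of -0.13, the list median was 5.99), of 27 synapse genes 25 (4.94), of 16 glutamatergic genes 15 (5.17), and all of 15 GABAergic (5.30) and 19 neurogenic genes (4.67). Gap43 was at least 560-fold and Fxyd6 at least 575-fold higher, Rtn1, a reticulon, rose 560-fold, Kif5c, a neuronal kinesin, 204-fold, Camk2b 164-fold and Atp1b1 159-fold. Syt1 was at least 311-fold, Gria2 at least 128-fold, Sst at least 263-fold, Gad1 at least 175-fold, Syn1 at least 172-fold and Slc17a7 at least 6.75-fold higher, and among transcription factors Myt1l was at least 150-fold and Bcl11a at least 72.0-fold higher. Mapt rose 54.7-fold, Map2 23.4-fold and Tubb3 at least 2.87-fold. Ion channels listed by symbol rose in 61 and fell in 7 of 77 cases (1.79), Kcnd2 by at least 80.2-fold. With genes not detected in MMC set at their bound, the median log2 fold changes of these 6 lists were 5.77, 3.77, 3.78, 4.16, 3.30 and 1.21. Camera gave them an adjusted p of 1.24e-09, 1.24e-09, 8.74e-07, 2.7e-08, 1.49e-09 and 1.49e-09, and adjusted p = 0.0302, 0.052, 0.0559, 0.0302, 0.0302 and 0.0302 with an estimated correlation. Astrocyte genes rose in 13 and fell in 2 of 15 (2.86, adjusted p = 0.000207, and adjusted p = 0.052 with an estimated correlation), with Slc1a3 at least 229-fold and Gfap at least 25.9-fold higher and S100b at least 18.1-fold lower. Ion pumps rose in 15 and fell in 5 of 23 (1.82, adjusted p = 0.009) and cholesterol synthesis rose in 18 of 21 (1.60, adjusted p = 0.000183), with Idi1 up 14.5-fold, Pmvk 7.01-fold and Ebp down by -1.43. With an estimated correlation adjusted p = 0.145 and 0.19 for these 2 lists.

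Lower in PNC were 22 of 28 p53 targets with 0 higher (relative median -1.20, and 11295 genes had an unadjusted p under 0.05), 22 of 27 secreted factors (-2.75) and 23 of 25 lysosome genes (-1.73). So were 12 of 16 interferon genes (-1.01), 18 of 22 mesenchymal genes (-2.99), 18 of 28 Myc targets (-0.52) and 48 of 63 ribosomal protein genes (-0.57). Higher in PNC were 3 of the secreted factors, led by Igfbp2 (at least 45.2-fold), 1 lysosome gene, Atp6v0d1 (0.49), 1 interferon gene, Irf9 (0.48), and 3 mesenchymal, 3 Myc target and 4 ribosomal protein genes. The changes were -4.70 for Gadd45a, -4.07 for Dram1, -7.41 and -7.10 for the chemokines Ccl7 and Ccl2, -5.58 for Ctsz, -4.41 for Ctsl, -4.56 for Ifitm3, -5.21 for Snai2, -4.13 for Fn1, fibronectin, -2.19 for Wdr43 and -2.43 for Rpl13a. The lowest called genes were Gpnmb (7.40 ± 2.19 against 15.17 ± 0.01), Ccl7, the chemokine Cxcl1 (6.81 ± 2.18 against 13.72 ± 0.58) and Cdkn2a (-6.82), and Insc, which orients dividing cells, was at least 57.7-fold, Ly6c1 at least 56.7-fold and Zfp985 at least 50.8-fold lower. These 7 lists had an adjusted p of 3.78e-05, 0.000273, 1.9e-06, 0.0122, 0.00268, 0.023 and 0.000149 in camera, and adjusted p = 0.223, 0.35, 0.113, 0.473, 0.544, 0.614 and 0.306 with an estimated correlation. The excess of bright line transcripts on PNC replicate 1, a median of 2.10% of their level in the line, enters these PNC means too: without that array the changes of Gpnmb and Cxcl1 were -9.03 and -8.17, against -7.76 and -6.92 with it (-7.11 and -6.33 without PNC replicate 2, -7.16 and -6.25 without PNC replicate 3).

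Lists of the cell cycle did not pass camera between PNC and MMC, but the G1/S and recombination repair lists passed fry (adjusted p = 0.00047 and 0.00194). Of 27 G2/M genes 13 were lower in PNC and 0 higher (relative median -0.31, adjusted p = 0.147). Of 28 G1/S genes 14 lower and 3 higher (-0.21, adjusted p = 0.156), and of 19 recombination repair genes 7 lower and 2 higher (-0.11, adjusted p = 0.221), the last with a median that turned to 0.10 after median scaling. Cdk1 (-1.91) and Cdt1 (-2.51) fell, Rrm2, a subunit of ribonucleotide reductase, rose 2.84-fold and Lig1, a DNA ligase, by 0.71, which was 0.45 without MMC replicate 3. Top2a (-0.61, adjusted p = 0.071) and Ccnb1 (-0.11, adjusted p = 0.71) were not called in the main fit, although Top2a was by the mean of its probes (-0.80, limma adjusted p = 0.0074). Top2a and Ccnb1 were called without MMC replicate 3 (-1.0 and -0.49), as was the G2/M list (median -0.71, and -0.43 with all arrays), which also passed with array weights (-0.57, adjusted p = 0.0143). Without MMC replicate 2 they stood at -0.29, 0.14 and -0.26, and Ccnb1 was also positive without MMC replicate 1 (0.01), after median scaling (0.02), with cyclic loess (0.11) and in the authors' matrix (0.14). Mki67 was called without MMC replicate 2 (0.75) or PNC replicate 1 (0.68), after median scaling (0.78) and cyclic loess (0.73) and in the authors' matrix (0.68). It was also called without background correction, with an offset of 50, with detection on all 9 arrays, with trended and robust moderation and with array weights (adjusted p = 0.0412, 0.0467, 0.0478, 0.0446 and 0.0023), but was 0.25 without MMC replicate 3 (adjusted p = 0.183). Cell cycle inhibitors went both ways (5 higher, 7 lower of 13, adjusted p = 0.63), with Cdkn1c at least 17-fold higher. Stem and progenitor genes (11 higher, 5 lower of 18, adjusted p = 0.335) included Fabp7, at least 98.0-fold higher, Sox2 (0.75, and 0.43 without MMC replicate 2) and Nes and Vim, with changes of -2.95 and -2.53. The oligodendrocyte list (7 and 3 of 11, 0.151, with a median of 1.24 that turned to -3.50 over the genes detected on all 9 arrays), microglia (2 and 4 of 6, 0.457), reference genes (4 and 10 of 14, 0.144), endothelial and mural genes (3 and 3 of 8, 0.959) and solute carriers (88 and 91 of 225, 0.63) also missed the threshold. The medians of the last 2, -0.07 and -0.11, turned to 0.32 and 0.10 after median scaling, and their means were -0.75 and 0.39. The microglia median of -1.65 turned to 0.07 without the filter on dim probes. Among single genes, Olig1 was at least 519-fold higher and Sox10 and Cd68 changed by -4.96 and -4.40 (Cd68 -3.80 without MMC replicate 2). Adjusted over the list alone, 13 G1/S genes, 11 G2/M genes, 23 secreted factors and 49 ribosomal protein genes were lower and 4 secreted factors higher, with the same counts for the other lists. As limits, the calls of the interferon, Myc target, ion pump and astrocyte lists ended when only genes detected on all 9 arrays were tested (adjusted p = 0.0879, 0.101, 0.159 and 0.159). Their medians went from -1.14 to -1.66, -0.65 to -0.61, 1.69 to 0.16 and 2.74 to 1.49, and this filter left 3030 genes higher in PNC. The call of the Myc targets also ended without MMC replicate 3 (median -0.49, and -0.65 with all arrays).

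The 2 comparisons with NSC were then set beside each other, since the series asks for a neuronal signature and its relation to arrest of the cycle. Genes higher than NSC in both MMC and PNC numbered 1190, against 998 for independent lists of these sizes, and genes lower in both 1833, against 1243. This balance depends on the scaling: 1465 genes were higher and 1512 lower in both after median scaling, 1695 and 1387 with cyclic loess and 1476 and 1607 in the authors' matrix. Genes higher in MMC and lower in PNC numbered 1077 (1241 for independent lists) and those lower in MMC and higher in PNC 502 (999), the last of which was 330 without NSC replicate 1 and 334 without NSC replicate 3. Across genes the fold changes had Pearson's r of 0.13 and Spearman's rho of 0.19. In 100 simulations of unchanged groups sharing the NSC arrays the mean r was 0.50. That value comes from the shared arrays alone, so it is no yardstick for groups that changed. Genes called in both with the same sign numbered 3023. The simulations held no change and so called almost no gene in both (mean of 0.01), which makes them no yardstick for this count either. The covariance was 0.166 against 0.0151 simulated, a difference of 0.151, and genes are not independent replicates. The 3 NSC arrays cannot be split into parts of at least 2, so part of the excess may come from the shared controls.

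Among genes higher in both, Svop, a synaptic vesicle protein, was at least 9.21-fold higher in MMC and at least 134-fold in PNC. Lyz1 and Lyz2, lysozymes with near-identical sequences, were at least 5.93-fold and 2.42-fold higher in MMC and at least 8.34-fold and 3.27-fold in PNC. Hs3st1, a heparan sulfate sulfotransferase, rose by 2.58 and 4.76 on the log2 scale, and Fam78b was at least 3.05-fold and 12-fold higher. Among genes lower in both, Tnnc2 changed by -4.53 in MMC and was at least 50.1-fold lower in PNC, and H3c3 was at least 6.94-fold and 8.70-fold lower. Aunip, an Aurora kinase partner, changed by -3.02 and -3.43, the cartilage collagen gene Col9a1 was at least 4.71-fold and 5.90-fold lower, and Tk1 changed by -2.65 and -3.49. Higher in MMC and lower in PNC were the complement gene C3 (2.63 and -4.29), S100b (2.51 and -2.50), the protease Plau (2.38 and -3.06, the last -3.83 without PNC replicate 1), Mmp10 (2.93 and -2.35) and the growth factor Btc (2.20 and -2.38). Lower in MMC and higher in PNC were the neurogenic factor Sox11 (-1.90 and 4.46), the actin nucleator Spire2 (-1.72 and 1.79), the microtubule regulator Stmn1 (-2.21 and 1.63), Asxl3 (-1.63 and 2.57) and Idi1 (-1.62 and 2.24). Of the 1190 genes higher in both, 754 were higher in PNC than in MMC, 105 lower and 331 not called.

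**Figure D3:**
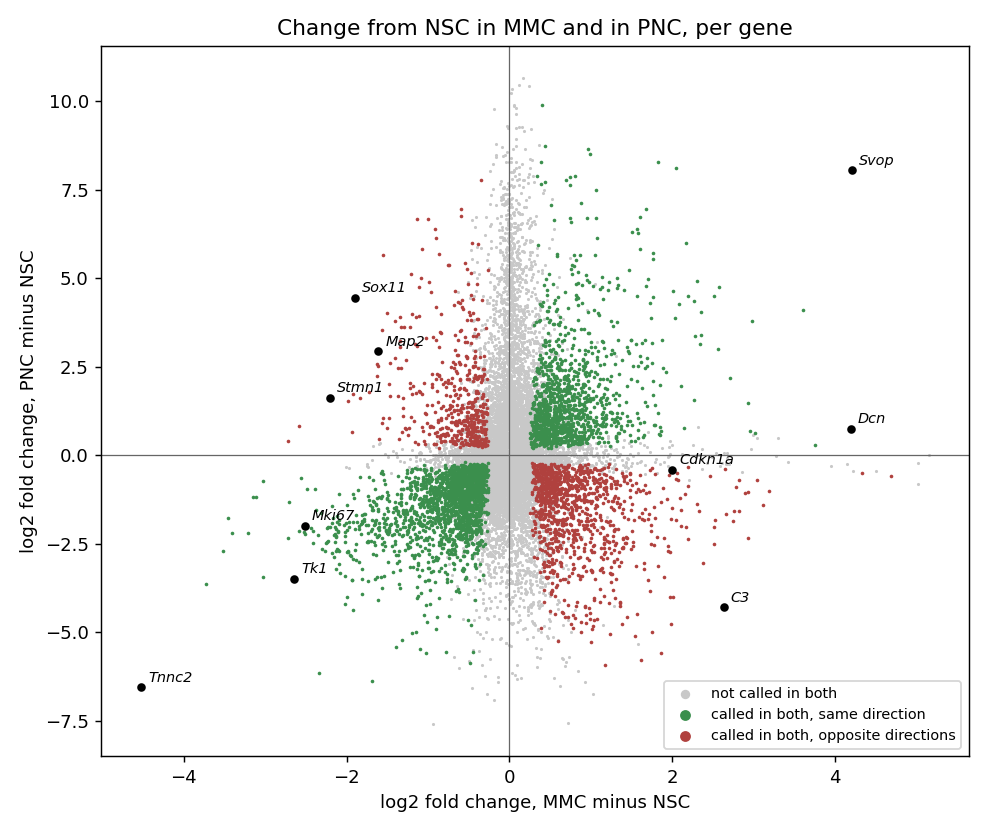
Log2 fold change of PNC against NSC (y axis) over that of MMC against NSC (x axis), a point per gene, with genes called in both comparisons coloured by direction. Genes lower in both (1833) outnumber those lower in MMC and higher in PNC (502), and Pearson's r across genes is 0.13.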

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

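Of the tests below, the one on mitomycin-treated cells as the source, the check on probes at background and the choice of the numbered probes were made only after the result was seen, and the bounds for the further set of dimmer probes were set after the value of the bright set was known.

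The following lists, which moved against NSC in both MMC and PNC, did so in opposite directions, and the difference between MMC and PNC was tested directly in the comparison of PNC with MMC. For p53 targets the median log2 difference of PNC from MMC was -1.33, for the lysosome list -1.85 and for cholesterol synthesis 1.48. Passing camera in that comparison was a condition for listing them here, so it adds no support (adjusted p = 3.78e-05, 1.9e-06 and 0.000183). With an estimated correlation adjusted p = 0.223, 0.113 and 0.19, so the calls rest on the preset correlation.

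For the counts of called genes, the 6 arrays of each comparison can be split into 3 and 3 in 10 ways, so the share of splits with a count as large cannot go under 0.05. The real split gave 5354 genes in MMC against NSC, 11864 in PNC against NSC and 10708 in PNC against MMC in fits of the 2 groups alone, and the highest count of the other splits was 0 in each, so that 1 of 10 splits reached the real count.

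A signal in probes that no gene test used came from a probe with a number for a name, ILMN_1221149. Its intensity over background averaged 29652 on the arrays of the line and was 1585, 17.1 and 8.42 on PNC replicates 1, 2 and 3, so that replicate 1 stood at 5.35% of the line's level. A second such probe, ILMN_1245887, stood at 28650 in the line and at 1492, 48.5 and 36.7 in PNC. Neither has a gene name in the tables used here, and none is inferred.

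ILMN_1221149 belongs to a wider pattern of transcripts of the line on the PNC replicate 1 array, while ILMN_1245887 is not in the set used here. That set held 43 named and unnamed probes, bright in the line and not detected on PNC replicates 2 and 3. They exceeded the mean of those 2 replicates by a median of 2.10% of the line's level, with 42 in excess. The excess ranged from -0.38% to 8.80%, so it was not the same share for every probe. More cells of other brain types stay open: 6 markers of microglia, vessels and mesenchyme not detected in the line differed by a median of 0.21 on the log2 scale, under the bound of 0.5 set beforehand, but spread from -0.05 to 0.94, with Lum of mesenchyme (0.94) and Fcer1g of microglia (0.64) above it. RNA of the line in that sample, from cells or from handling, is a candidate explanation. A further set of 80 dimmer probes had a median excess of 2.69% (quartiles 1.66% and 4.19%) with 79 in excess. Over 20471 probes at background the median difference was 0.15 intensity units, against 13.1 over the 80 probes. With PNC replicates 2 and 3 as the odd array, 55 and 53 probes gave -0.90% and -1.0%. Those values were taken against means that include PNC replicate 1, whose excess lowers them, so they add no support. Whether treated or untreated cells were the source stays open. All 6 probes detected in MMC alone were in excess (median 2.74% of the MMC level), but the 2 of them detected on PNC replicate 1 both belong to Prl2c3, which has near-identical copies, and the other 4 lay near background. The 2 read 73.6 and 49.5 there against 14 and 9.23 in NSC, more than a few percent of untreated cells would add. The labels put no PNC sample in a group of its own, so the design gives no biological explanation for this array beyond the cell types tested above. Immediate-early genes were also higher on this array, as given below, and a link to this pattern was not tested.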

How the results depend on the processing

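The background from the lower side of the signal mode was the only alternative chosen after seeing the data, and a block by array chip could not be run since no label gives the chip. Of 329 results for genes reported, 297 kept direction and side of the threshold under every alternative run for them, as did 41 of 78 list medians. Over all alternatives, 105 of 7080 gene values lost their call, 25 gained one, 12 moved and 1 reversed, and of 1710 list medians 25 lost it, 24 gained it and 65 moved. The reversals were Actb at -1.28 (PNC against NSC) with the mean of its probes, and the cell cycle inhibitors in PNC against NSC, higher in fry (adjusted p = 0.00127), which compares with no other genes. Detection on all 9 arrays, which tests fewer genes, left 2955 genes higher in PNC than NSC and 3030 higher than in MMC. Array weights, whose estimate stopped before convergence with weights of 20.6, 0.22 and 0.30 for MMC replicates 1, 2 and 3, gave 4702 genes higher and 4692 lower in MMC than NSC, 2169 higher and 2936 lower in both, 1920 higher in MMC and lower in PNC, and 1104 the other way. Calling only changes of at least 2-fold gave 665 higher and 562 lower in MMC than NSC, 3309 and 3585 in PNC than NSC, 3197 and 3347 in PNC than MMC, 169 higher and 369 lower in both, and 211 and 58 in opposite directions. With an estimated correlation 0, 6 and 4 lists passed in the comparisons of MMC with NSC, PNC with NSC and PNC with MMC, where 10, 17 and 16 passed with the preset one, and fry called 16, 25 and 24 of 26. The count lower in MMC and higher in PNC than NSC was 330 to 512 over the arrays left out (lowest without NSC replicate 1), and the cause was not tested. Leaving out arrays gave 2167 to 2868 genes higher and 2086 to 2781 lower in MMC than NSC, and the correlation across genes of the 2 comparisons with NSC was 0.12 to 0.19 over the alternatives. The replicate number as a block gave 2781 and 2841 genes for MMC against NSC, and arrays of the same number correlated in their deviations at 0.12, -0.01 and -0.03 in MMC and NSC, 0.06, 0.12 and 0.18 in PNC and NSC, and 0.09, 0.07 and 0.15 in PNC and MMC. The signal over background limits the fold of dim genes, which shrank without background correction, with an offset of 50 and in the authors' matrix.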

Other observations

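The gene families, the immediate-early genes, the tests of histone genes shared with PNC and the histone pattern itself were chosen only after values were seen.

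Genes were also grouped by the leading letters of their symbols into 203 families of at least 8 tested genes. In camera 19, 20 and 7 families passed the threshold in MMC against NSC, PNC against NSC and PNC against MMC, and 0 did with an estimated correlation. In MMC, 21 of 45 Mrpl genes, which encode proteins of the mitochondrial ribosome, fell and 0 rose (median -0.33, adjusted p = 3.98e-05, and adjusted p = 0.504 with an estimated correlation), as did 10 of 16 Nup genes of the nuclear pore (-0.59, adjusted p = 9.63e-05, and adjusted p = 0.504 with an estimated correlation). In PNC against NSC 15 of 17 clustered protocadherins of the Pcdhb family rose (median 1.96 relative to all genes, adjusted p = 0.0021), while 8 of 9 annexins (-3.22, adjusted p = 0.0265) and 8 of 8 Klra genes (-3.02, adjusted p = 0.0297) fell, each with adjusted p = 0.652 with an estimated correlation. The Klra genes are close paralogs, and their probes are not independent.

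Immediate-early genes, which respond within minutes to stimulation, were higher on PNC replicate 1 than the mean of PNC replicates 2 and 3, Fos 5.40-fold, Npas4 6.32-fold, Egr1 4.62-fold and Arc 4.52-fold. The medians of lists against NSC also spread within MMC: over replicates 1, 2 and 3 they were 0.40, 0.90 and -0.08 for mesenchymal genes, 0.55, 0.99 and 0.32 for interferon genes and -1.57, -1.37 and -2.37 for G2/M genes.

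Of 61 histone genes tested, 16 were higher and 32 lower in MMC than in NSC, with H2b genes mainly higher (9 of 12) and H3 genes lower (10 of 11). After merging probes that share at least 40 bases, the higher genes still fell into 15 groups and the lower into 25. In 1 group both occurred, with H2ac15 lower and H2ac19 higher. Probes were compared only with each other and not with the transcripts of other copies, so signals shared between paralogs stay open. A shift common to cells that have left the cycle stays open, since PNC differs from the line in cell type as well. Of the 16 higher genes 4, or 25%, were also higher in PNC and 6 lower, against 5 of the other 45 higher (11.1%). Of the 32 lower genes 28, or 87.5%, were also lower in PNC, against 16 of the other 29 (55.2%). The mitomycin treatment and the longer time in culture may each have a part, and the design gives no sample that parts them.

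Sox10, a gene of oligodendrocytes and of the neural crest lineage, was bright on the NSC arrays at 12.91 on the log2 scale. Of 17 further crest and Schwann genes 8, or 47.1%, were detected on all 3 NSC arrays, against 1 of 13 forebrain genes (7.69%) and 2 of 13 hindbrain genes (15.4%), with a two-sided Fisher's exact p of 0.0138 for the first list against the others. These shares do not give levels: the 2 hindbrain genes, En1 and Irx3, stood at 11.60 and 6.98 in NSC. The 8 crest and Schwann genes lay between 5.96 (Sox8) and 11.82 (Ngfr). A crest or Schwann character of the line may explain the bright Sox10, but the share missed the bound of 50% set beforehand, and 35.3% of the same genes were detected in PNC, so the question stays open. A single probe reading another transcript also stays open, since the gene has 1 probe on the array.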
